A study of Mus musculus with 6 samples.

How the data were processed

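Poly-A RNA was prepared from magnetically purified splenic B cells after 6 h of stimulation, made into libraries with a TruSeq RNA kit and sequenced on a HiSeq2000 with 100 bp reads, per the labels' protocols. The deposited table held raw counts per gene symbol for each of the 6 libraries, in whole numbers that summed to different totals. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.4, Cufflinks 2.0.2 and the mouse genome build mm9, with no role or order. The counting tool, the gene annotation and whether counting used strand are not given in the sources used here. The plan written before the data were examined had assumed FPKM values and named edgeR for the case of counts, so edgeR was used and the alternatives planned for FPKM were carried over to counts or CPM.

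The table listed 23284 symbols, of which 16034 had a count above 0. Of the symbols, 25 looked like calendar dates, a known effect of spreadsheet software, and were not named. Each column was matched to its sample by title. Totals ran from 13779355 counts in REL-deleted replicate 3 to 22701760 in REL-deleted replicate 1, so that 3 counts, the floor used here, correspond to 0.132 to 0.218 CPM. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates were compared before averaging with a chi-square statistic per degree of freedom over genes with at least 20 counts. It lay between 2.52 and 5.22 for the 6 pairs within groups and between 13.7 and 19.7 for the 9 pairs between groups, so that every library differed from the others by more than sampling noise and was counted separately.

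REL-deleted libraries were compared with control libraries in 1 factor without covariates. Genes were filtered with filterByExpr, leaving 11635 genes with 99.95% of the counts, scaled by TMM (factors 0.9953 to 1.003) and tested with glmQLFit and glmQLFTest of edgeR 4.0.16 in R 4.3.3. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were the absolute log2 fold change divided by the square root of the F statistic. The biological coefficient of variation was 4.18%. CPM were computed with the TMM factors. For Rel an exact permutation test over 20 assignments was added. For genes with 1 to 3 counts in a group the ratio of summed counts, scaled to library size, was given with an exact 95% interval.

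The named genes followed a rule set before the data were examined. It took Rel, Rela, Relb, Nfkb1, Nfkb2, Myc, Irf4, Bcl2l1 and Ccnd2, the 10 largest decreases and 10 largest increases among called genes whose groups did not overlap, up to 4 members of each fixed list by unadjusted p, and the 2 most abundant members of each list of another cell type. Gene models without a proper name, small RNAs and receptor segments were counted but not named under this rule. The 31 fixed lists covered NF-kB, survival, cell cycle, biosynthesis, metabolism, activation, B cell programmes, stress and other cell types, and 28 had the 5 tested members needed for a set test. These were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and a variance trend, adjusted over the lists. Camera with an estimated correlation and fry were run beside it.

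The tests were tried on simulated counts drawn from the means and library sizes of these libraries. Over 11555 genes, edgeR recovered 16.3% of genes changed 1.1-fold, 65.3% at 1.3-fold, 82.0% at 1.5-fold and 93.8% at 2-fold, and 9.35% of its calls were false. In this single draw 48 to 50 genes were changed at each fold and 13 calls were false. In the real data 23.3% of genes were called. These shares depend on how many genes change, so they do not carry over to the real calls. Camera recovered 5 of 5 shifted lists with 0 of 15 false calls, whichever correlation was used. Genes were drawn independently and the lists at random, while the real lists had estimated correlations of up to 0.437. The simulation therefore cannot tell which correlation setting suits the real lists.

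Alternatives covered the replicate number as a block, other filters, scalings, variance models and library weights, limma on log2 CPM with 0.1 or 5 added, DESeq2 1.42.0, other thresholds and each library left out in turn. Thinning to the smallest total, removal of trends with GC content and transcript length, and removal of other cells' markers with genes under 5 CPM in control libraries were added after the data were seen. GC content, length, exon overlaps and shared sequence came from GENCODE M21 and gene order from RefSeq on GRCm38. Since the counts were made on mm9, no coordinates are printed. Genes whose exons overlap on the opposite strand cannot be separated where counting ignored strand, and the counting of reads that map to several places is not stated.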

Results

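The data set held RNA sequencing counts from mouse splenic B cells in 6 libraries. Spleen B cells were purified with magnetic beads from 12-week-old littermates and cultured for 6 h with antibodies against CD40 and against IgM, which engage a costimulatory receptor and the B cell antigen receptor. In 3 libraries the mice carried the CD19-Cre transgene alone (control), and in 3 they also carried floxed copies of Rel, so that Cre removes this gene in B cells (REL-deleted). Rel encodes c-Rel, an NF-kB transcription factor subunit that is induced by both stimuli. Counts per library totalled 20694980, 21178280 and 21861562 in control libraries and 22701760, 17350289 and 13779355 in REL-deleted libraries. The 10 most abundant genes took between 3.77% and 3.85% of the counts of each library. The labels do not say that each library came from a separate mouse, so p-values measure only the spread between these libraries, which may be technical. Levels are given as normalised read counts scaled to library size (CPM), mean ± SD with n = 3 per group.

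The targeted gene was examined first. Rel stood at 422.9 CPM in control libraries (range 420 to 426) and at 34.8 CPM in REL-deleted libraries (range 32.7 to 36.8), which is 8.23% of the control level. The log2 fold change was -3.61 (SE 0.0457), with an adjusted p of 2.12e-20 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. No library of either group overlapped the other group, and the exact two-sided permutation test over 20 assignments gave p = 0.1, the smallest value that 3 against 3 allows. Which exons the deletion removes is not given in the sources used here, so reads of any remaining exons are included in this level.

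The main comparison asked which transcripts of stimulated B cells differ when c-Rel is missing. Loss of Rel was accompanied by much lower levels of Bcl2l1, which encodes the survival protein BCL-XL, of Il2ra, which encodes the high-affinity IL-2 receptor chain CD25, and of the G1 cyclin gene Ccnd2. Bcl2l1 fell 9.04-fold, from 100.1 ± 5.27 to 10.9 ± 1.06 CPM, Il2ra fell 5.43-fold, from 260.3 ± 5.49 to 47.9 ± 2.39 CPM, and Ccnd2 fell 2.60-fold, from 194.2 ± 4.90 to 74.8 ± 3.39 CPM. Of the fixed gene lists, 19 of 28 genes of cholesterol and fatty acid synthesis and 19 of 45 of ribosome biogenesis were lower, and 22 of 31 genes tied to quiescence, 22 of 38 of cytokines and their receptors and 15 of 23 of the unfolded protein response were higher. Markers of other cells, most of them scarce, were higher too. Of the tested genes, these were 11 of 14 for T cells, 9 of 13 for myeloid cells and 5 of 6 for NK cells. A gene scarce in control libraries passed the filter only where REL-deleted libraries held it, which can raise these shares. The myeloid markers Mpeg1 and Cd68 did not rise. They stood at 102.9 and 10.7 CPM in control libraries, against 0.659 CPM for S100a9, and which cells supplied them was not tested. Every one of these list calls was lost with an estimated correlation, at adjusted p = 0.0651 for all but cytokines (adjusted p = 0.0912) and the unfolded protein response (adjusted p = 0.138). For myeloid markers the estimate (-0.024) lay below the preset 0.01, so a higher correlation was not the reason for that loss.

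Of 11635 genes tested, 2712 (23.3%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 1506 higher and 1206 lower in REL-deleted libraries. Most changes were small, with a median absolute log2 fold change of 0.28 among called genes. A change of at least 2-fold was seen in 224 of them, 144 higher and 80 lower, and 88 of the 144 lay under 1 CPM in control libraries. This count depended on the treatment of scarce genes, and was 325 with no filter on low counts, 65 at a mean of at least 5 CPM and 36 with limma on log2(CPM + 5). Principal component 1 held 57.7% of the variance and separated the groups. Without the markers of other cell types and genes under 5 CPM in control libraries, an alternative chosen after the data were seen, 1188 genes were higher and 1154 lower, 67 of them at least 2-fold.

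**Figure D1:**
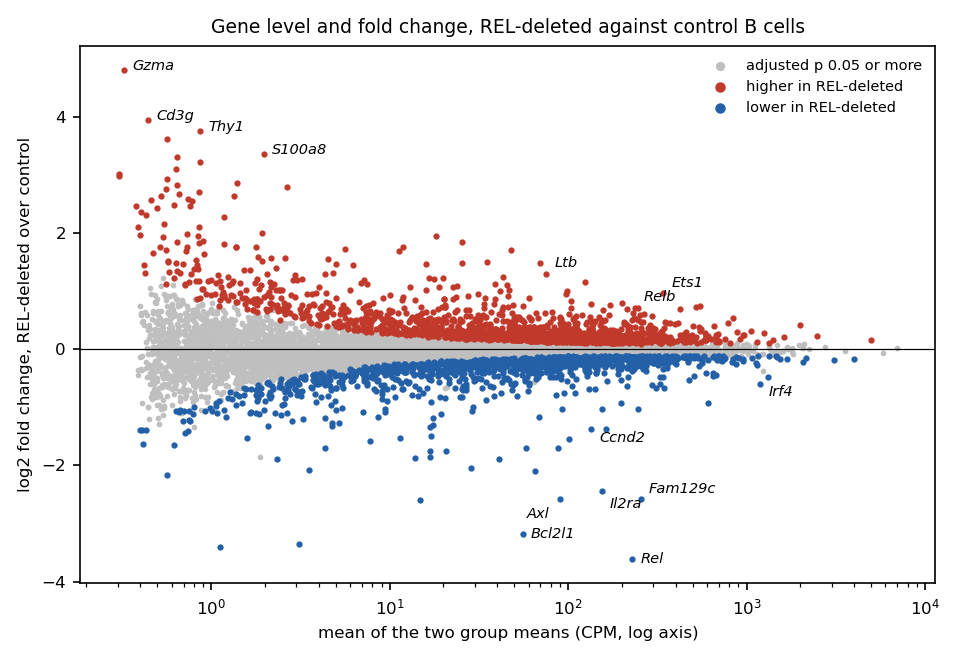
Mean level (CPM, log axis) against log2 fold change of REL-deleted over control libraries for each of the 11635 tested genes, coloured by the call at an adjusted p of 0.05. The 1506 higher and 1206 lower genes are mostly within small fold changes, and the largest increases sit at the lowest levels.

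After Rel, the 10 largest decreases by the naming rule were led by Mgll, a lipase gene that was scarce throughout (2.04 ± 0.178 to 0.194 ± 0.0531 CPM), and Sytl3 (5.6 ± 0.173 to 0.581 ± 0.250 CPM), which overlaps Ezr on the opposite strand and is uncertain for that reason. Mgll overlaps an unnamed gene model in the same way. Among abundant genes, the receptor tyrosine kinase gene Axl fell by 2.58 on the log2 scale, from 153.7 ± 6.65 to 25.5 ± 1.88 CPM. Fam129c fell by 2.57, from 435.9 ± 2.82 to 73.2 ± 2.50 CPM, and shares exon sequence with Pgls on the same strand. The G protein subunit gene Gng4 dropped by 2.09, from 105.1 ± 1.22 to 24.7 ± 0.552 CPM, and the glutamate receptor gene Grm6 dropped by 2.59, from 25.4 ± 2.74 to 4.17 ± 0.226 CPM. Chst1 was lower at 0.938 ± 0.114 and 0.189 ± 0.175 CPM. Adjusted p-values of these 7 genes in edgeR's quasi-likelihood test ran from 3.69e-19 for Fam129c to 0.00209 for Chst1.

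The 10 largest increases were all of genes that control libraries hardly held. Gzma, a granzyme gene of cytotoxic lymphocytes, had 1 count in the control group and 33 in the REL-deleted group, a ratio of 39.1 after scaling to library size (95% exact interval 6.54 to 1590, counting error only). The T cell receptor complex gene Cd3g had 3 and 44 counts, a ratio of 17.4 (5.57 to 87.4). Thy1 rose from 0.110 ± 0.0303 to 1.61 ± 0.283 CPM and Cd3d from 0.110 ± 0.0303 to 1.17 ± 0.298 CPM, both T cell markers. The granulocyte genes S100a8 (0.346 ± 0.0797 to 3.59 ± 0.535 CPM) and Ngp (0.154 ± 0.145 to 1.57 ± 0.287 CPM), the chemokine gene Ccl6 and the lymphocyte transcription factor gene Eomes also rose. Capn11 reached 1.05 ± 0.236 CPM and Gprc5b, whose exons overlap Iqck on the opposite strand, reached 1.14 ± 0.208 CPM.

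Among the gene lists fixed before the data were examined, the NF-kB family and feedback list had 14 higher and 3 lower members of 24 tested, and the same 14 and 3 adjusted over the list alone. Relb, which encodes a partner of the alternative pathway, rose by 0.72 on the log2 scale (178.7 ± 6.79 to 294.5 ± 15.6 CPM). The other family members rose less, with log2 fold changes of 0.31 for Nfkb1, 0.20 for Rela and 0.17 for Nfkb2. The adaptor gene Traf3 rose by 0.45, and the kinase gene Ikbke fell 2.47-fold, from 25.0 ± 0.821 to 9.97 ± 1.90 CPM. The list median was 0.18 and its mean -0.03, which differ in sign, and without the deleted gene Rel, itself 1 of the 3 lower members, the mean was 0.12. The list was called up by camera with a preset correlation (adjusted p = 0.00189), and this call was lost at adjusted p = 0.272 with an estimated correlation.

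**Figure D2:**
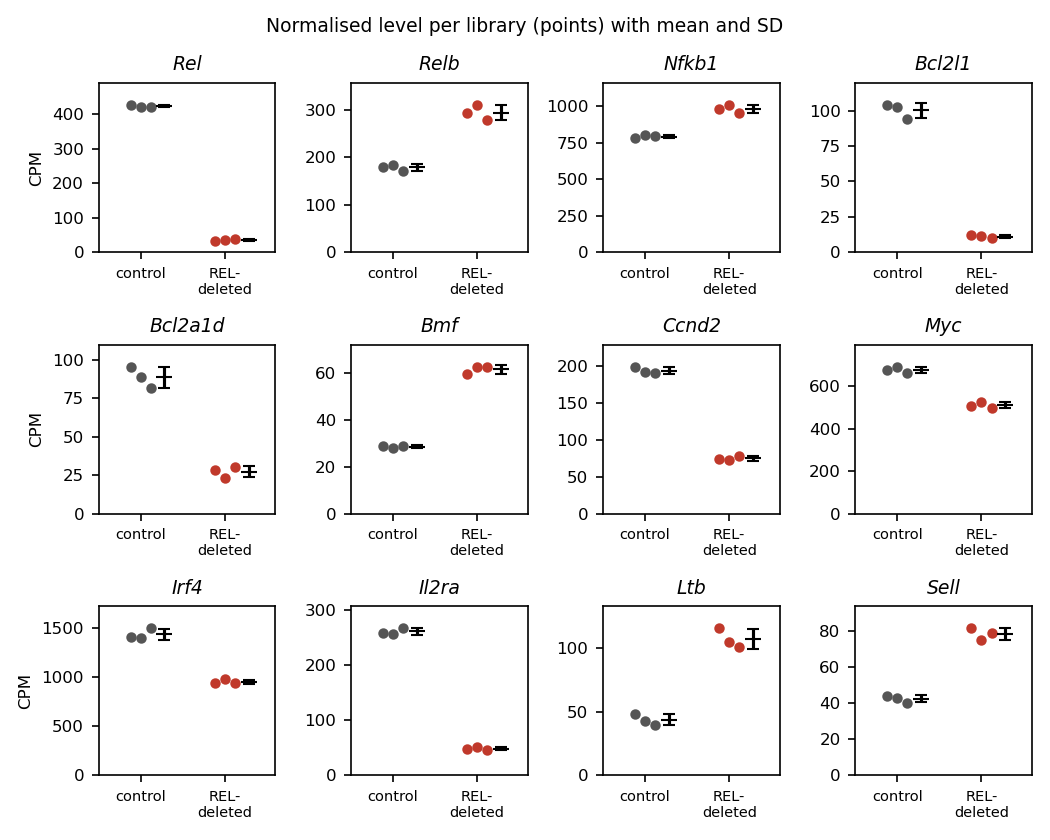
Levels (CPM) of 12 genes in each of the 6 libraries, points for single libraries and bars for the group mean and SD. Rel, Bcl2l1, Bcl2a1d, Il2ra, Ccnd2, Myc and Irf4 are lower and Relb, Nfkb1, Bmf, Ltb and Sell higher in the 3 REL-deleted libraries, with no overlap between groups.

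In the survival and apoptosis list, 6 of 24 tested genes were higher and 7 lower (7 and 8 adjusted over the list alone), and the list as a whole was not called (adjusted p = 0.116). Besides Bcl2l1, the antiapoptotic paralogs Bcl2a1d and Bcl2a1b fell by 1.70 and 1.03 on the log2 scale. Their sequences are nearly identical, so the split of reads between them is uncertain. Bmf, which encodes a proapoptotic BH3-only protein, rose 2.15-fold, from 28.7 ± 0.513 to 61.7 ± 1.92 CPM. The antiapoptotic genes Bcl2 and Mcl1, chosen after their values were seen, rose by 0.42 and 0.17 on the log2 scale. In the G1 to S list, 7 of 35 genes were higher and 5 lower, also adjusted over the list alone, with no call for the list (adjusted p = 0.168). Its lower members included Ccnd2, whose exons overlap unnamed gene models on the opposite strand, the cyclin-dependent kinase inhibitor gene Cdkn1a (26.3 ± 1.32 to 14.6 ± 0.948 CPM), Mybl2 and E2f2, the last 2 at 0.88 and 0.58 below control on the log2 scale. Its 7 higher members included Myb, Cdt1 and Cdk6, chosen after their values were seen, at log2 fold changes of 0.25, 0.23 and 0.25.

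Ribosome biogenesis genes moved one way only, with 0 higher and 19 lower of 45 (0 and 21 adjusted over the list alone). The transcription factor gene Myc fell by 0.41 on the log2 scale, from 676.4 ± 15.2 to 510.0 ± 13.9 CPM, and the nucleolar genes Nolc1, Rrp1b and Bop1 fell by 0.29, 0.24 and 0.19. The list was called down by camera with an adjusted p of 1.43e-08 (adjusted p = 0.0651 with an estimated correlation). Cholesterol and fatty acid synthesis showed 0 higher and 19 lower of 28 genes, 0 and 23 adjusted over the list alone. The stearoyl-CoA desaturase genes Scd2 and Scd1 fell by 0.61 and 0.47, and the sterol reductase genes Dhcr24 and Dhcr7 by 0.42 and 0.30. Camera called this list down (adjusted p = 5.15e-12, and adjusted p = 0.0651 with an estimated correlation).

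Nucleotide synthesis had 2 higher and 10 lower of 30 genes (2 and 14 adjusted over the list alone), and was called down with adjusted p = 0.00119, which became adjusted p = 0.269 with an estimated correlation. Rrm2, a ribonucleotide reductase subunit gene, fell by 0.82 and Atic, of purine synthesis, by 0.23, while Ctps2 and Adssl1 rose by 0.38 and 0.66. Amino acid transport, serine and one-carbon metabolism had 3 higher and 13 lower of 33 (5 and 14 adjusted over the list alone), with adjusted p = 0.00236 and adjusted p = 0.269 with an estimated correlation. The asparagine synthetase gene Asns fell by 0.46, Shmt1 by 0.26 and the transporter gene Slc7a5 by 0.21, and the cystine transporter gene Slc7a11 rose by 0.76.

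Aminoacyl-tRNA synthetases and translation initiation had 1 higher and 3 lower of 35 genes, and 0 and 0 in edgeR's test when adjusted over the list alone. The list was called down at adjusted p = 0.0326 (adjusted p = 0.138 with an estimated correlation), and the call ended without control replicate 1 (adjusted p = 0.0678) and with quantile normalization (adjusted p = 0.0553). Glycolysis and glucose uptake was not called (adjusted p = 0.0829), with 1 higher and 5 lower of 20 genes, 1 and 6 adjusted over the list alone. Its examples were Hk2, Ldha and Pkm2, lower by small amounts at log2 fold changes of -0.24, -0.19 and -0.16, and Hif1a at 0.21. The tricarboxylic acid cycle and import list had 3 higher and 5 lower of 33 genes, also adjusted over the list alone (adjusted p = 0.087, and called down at 0.0411 without control replicate 3 and at 0.047 with no filter on low counts), and oxidative phosphorylation had 0 higher and 1 lower of 56, with 0 and 0 adjusted over the list alone (adjusted p = 0.696). The 1 gene was Cyc1, at a log2 fold change of -0.14, whose call was lost in 3 of the 6 leave-one-out fits.

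Activation markers and costimulation had 10 higher and 17 lower of 36 genes, also adjusted over the list alone, and was called down (adjusted p = 0.00538, and adjusted p = 0.0974 with an estimated correlation). Beside Il2ra, the transcription factor gene Irf4 fell by 0.59, from 1433 ± 57.1 to 951 ± 21.9 CPM, and the adhesion receptor gene Cd44 fell by 0.55. The costimulatory genes Icosl and Tnfrsf9 rose by 1.25 and 1.23, from 25.6 ± 0.778 to 60.6 ± 2.21 CPM and from 10.0 ± 0.622 to 23.4 ± 2.03 CPM. Cytokines, chemokines and their receptors had 22 higher and 6 lower of 38 genes (22 and 8 adjusted over the list alone), with adjusted p = 1.04e-05 and adjusted p = 0.0912 with an estimated correlation. The lymphotoxin beta gene Ltb rose 2.48-fold, from 43.4 ± 4.31 to 107 ± 7.76 CPM, Il9r rose by 0.80 and the chemokine receptor gene Cxcr4 by 0.58 on the log2 scale, and Tnfrsf13c, which encodes the BAFF receptor, fell by 0.66. Summed T cell markers (101 ± 3.67 to 165 ± 6.44 CPM) and NK cell markers (4.07 ± 0.829 to 12.8 ± 0.242 CPM) were higher in the same libraries. Most of the T cell sum was Lck and Il7r. Il2rb, 1 of the higher genes of the cytokine list, is also in the NK cell list.

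Quiescence and FOXO/KLF2 targets had 22 higher and 1 lower of 31 genes, also adjusted over the list alone, and were called up (adjusted p = 1.18e-10, and adjusted p = 0.0651 with an estimated correlation). The homing receptor gene Sell rose by 0.89 (42.4 ± 2.09 to 78.4 ± 3.39 CPM), the antiproliferative gene Btg2 by 0.72, the BH3-only gene Bcl2l11 by 0.47 and Tcf7, which T cells also express, by 1.73 (2.59 ± 0.622 to 8.68 ± 0.853 CPM). The summed level of T cell markers was higher in the same libraries, at 165 ± 6.44 against 101 ± 3.67 CPM. Most of this sum was Lck (73.0 CPM in control libraries) and Il7r (14.2 CPM), and Il7r is also in the quiescence list. Thy1 stood at 0.110 CPM in control libraries, so the sum may not be a measure of T cell RNA. The p53 target list had 4 higher and 11 lower of 21 genes (4 and 12 adjusted over the list alone), with adjusted p = 0.000234 and adjusted p = 0.0651 with an estimated correlation. Psrc1, Phlda3 and Cdkn1a fell by 1.52, 1.57 and 0.84, and Btg2 rose. The unfolded protein response and chaperone list had 15 higher and 0 lower of 23, also adjusted over the list alone (adjusted p = 2.27e-06, and adjusted p = 0.138 with an estimated correlation), with log2 fold changes of 0.32 for Calr, 0.28 for Edem1, 0.25 for Hsp90b1 and 0.20 for Xbp1.

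**Figure D3:**
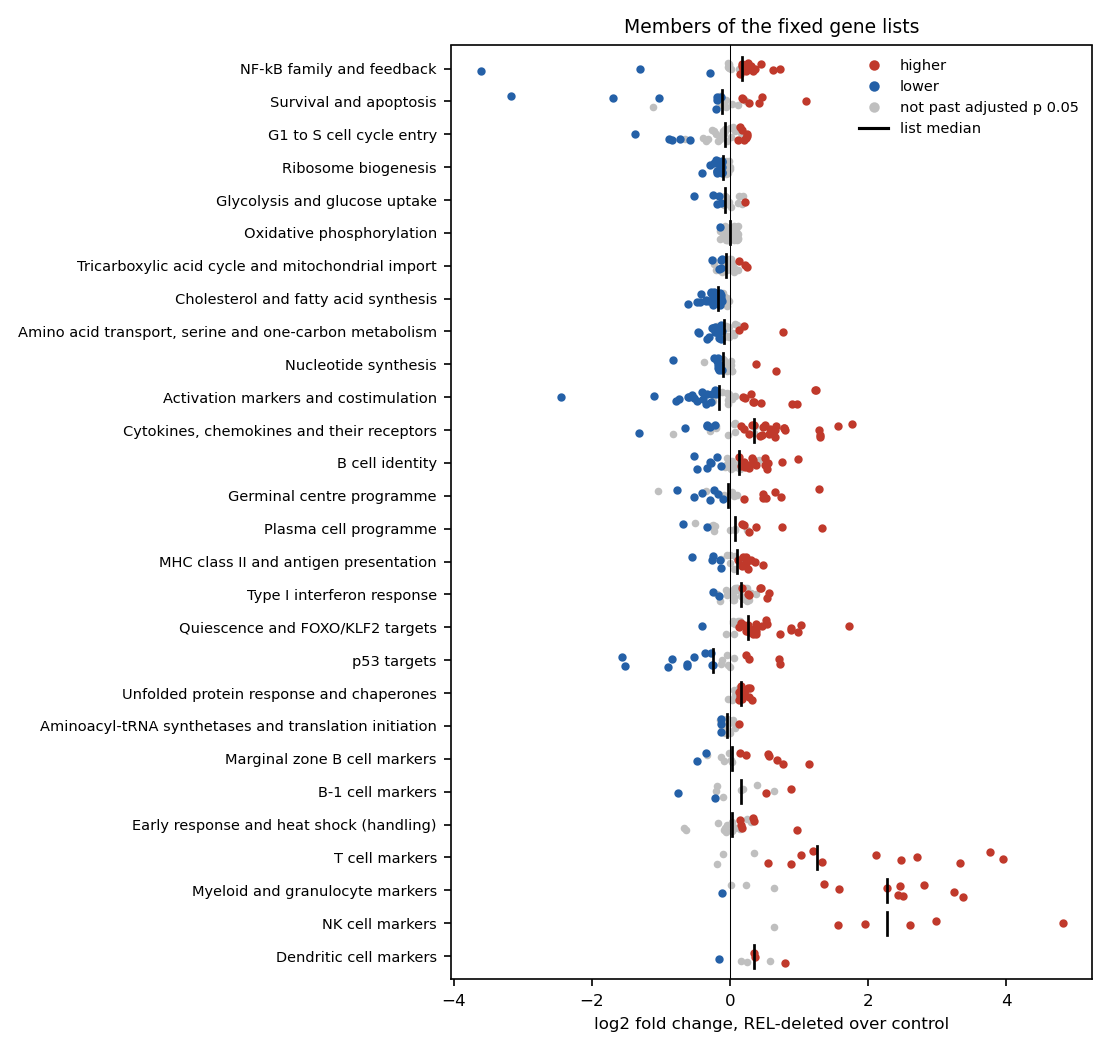
Log2 fold change of REL-deleted over control libraries for the tested members of the 28 gene lists tested as sets, 1 point per gene with the list median marked. Cholesterol and ribosome biogenesis genes lie mostly below 0 (medians -0.18 and -0.09) and T cell, myeloid and NK cell markers above it (medians 1.26, 2.28 and 2.28).

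B cell identity genes were also mixed, with 15 higher and 7 lower of 34 (17 and 7 adjusted over the list alone). The transcription factor gene Ets1 rose by 0.98, from 229 ± 5.33 to 450.8 ± 5.53 CPM, the coactivator gene Pou2af1 by 0.76, Faim3 by 0.55 and Fcrla by 0.51. The list was called up (adjusted p = 0.00146, and adjusted p = 0.269 with an estimated correlation). The germinal centre list had 7 higher and 7 lower of 20 (7 and 8 adjusted over the list alone), was not called (adjusted p = 0.722), and held Mef2c, Bcl6, Rgs1 and S1pr2, which rose by 0.48, 0.48, 0.73 and 1.29. Its lower members included Plxnb2 and the methyltransferase gene Ezh2, which were chosen after their values were seen and fell by 0.41 and 0.29. The plasma cell list had 6 higher and 2 lower of 17, also adjusted over the list alone (adjusted p = 0.277). In it Igj, the immunoglobulin J chain gene, fell by 0.69, Slamf7 fell by 0.33, and Pou2af1 and Cd28 rose, the latter from 2.74 ± 0.136 to 6.91 ± 0.660 CPM. Cd28 is also in the list of T cell markers, most of which were higher in the same libraries.

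MHC class II and antigen presentation had 10 higher and 5 lower of 22, also adjusted over the list alone (adjusted p = 0.0856), among them H2-Eb2 and Tapbp, which rose by 0.47 and 0.37, and Ifi30 and the class II transactivator gene Ciita, which fell by 0.55 and 0.26. The type I interferon list had 7 higher and 2 lower of 35, also adjusted over the list alone, and was called up at adjusted p = 0.0214 (adjusted p = 0.542 with an estimated correlation). This call was lost without control replicate 3 (adjusted p = 0.177), REL-deleted replicate 1 (0.0863) or REL-deleted replicate 3 (0.0724). Irf1 and Ddx58 rose by 0.54 and 0.57, Irf7 by 0.43 and Irf9 by 0.17. Marginal zone B cell markers had 7 higher and 2 lower of 15 (7 and 4 adjusted over the list alone, adjusted p = 0.0856, and called up at 0.0346 with no filter on low counts), with Plac8, Cd9 and Cd36 up by 0.76, 0.55 and 0.67 and Asb2 up 2.21-fold. B-1 cell markers had 2 higher and 2 lower of 11 (3 and 2 adjusted over the list alone, adjusted p = 0.528), where Ptpn22 and Spn rose by 0.53 and 0.88 and Cd5 and Ahr fell by 0.76 and 0.22. Early response and heat shock genes had 6 higher and 0 lower of 21, also adjusted over the list alone (adjusted p = 0.116), with Egr1 at 0.33. This list, which responds to the handling of cells, was called up without control replicate 1 (adjusted p = 0.0161) and without REL-deleted replicate 3 (adjusted p = 0.022).

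Among markers of other cell types, 11 of 14 tested T cell markers were higher and 0 lower (12 and 0 adjusted over the list alone), 9 of 13 myeloid markers higher and 1 lower (11 and 1), and 5 of 6 NK cell markers higher and 0 lower (5 and 0). Of the listed genes in the table, 14 of 19, 13 of 24 and 6 of 12 passed the filter. A gene scarce in control libraries passed only where REL-deleted libraries held it, which can raise these shares and the set tests on them. Camera called these 3 lists up with adjusted p of 7.46e-09, 2.27e-06 and 8.58e-05, and each had adjusted p = 0.0651 with an estimated correlation. The most abundant T cell markers, Lck and Il7r, rose from 73.0 ± 2.67 to 107 ± 5.52 CPM and from 14.2 ± 0.754 to 25.9 ± 2.61 CPM. The most abundant myeloid markers did not rise. Control libraries held them far above S100a8, S100a9, Csf3r and Ngp, and which cells supplied them was not tested. The sum of all listed myeloid markers was 128 ± 1.33 CPM in control and 139 ± 4.1 CPM in REL-deleted libraries. Mpeg1 stood at 102.9 ± 1.16 and 94.5 ± 4.01 CPM, with a call that was lost in 5 of 6 leave-one-out fits, and Cd68 at 10.7 ± 1.38 and 10.8 ± 0.284 CPM, not passing. S100a9 and Csf3r rose from 0.659 ± 0.208 to 4.68 ± 0.429 CPM and from 0.407 ± 0.0433 to 1.96 ± 0.318 CPM, and the NK cell genes Il2rb, Klrk1 and Klrd1 reached 6.75 ± 0.686, 1.28 ± 0.0940 and 1.33 ± 0.170 CPM. Dendritic cell markers had 3 higher and 1 lower of 7 (5 and 1 adjusted over the list alone), with adjusted p = 0.0305 and adjusted p = 0.269 with an estimated correlation. This call was lost without REL-deleted replicate 1 (adjusted p = 0.0686) and at a mean of at least 5 CPM (adjusted p = 0.0964). Pacsin1 and Ly6d rose by 0.36 and 0.35, and the call for Ly6d was lost in edgeR's robust quasi-likelihood test (adjusted p = 0.0775). Of 4 erythroid and platelet markers tested, Car2 was lower at 7.26 ± 0.394 and 5.37 ± 0.855 CPM, a call that was lost without REL-deleted replicate 1 (adjusted p = 0.0795), and the only stromal or endothelial marker tested, Pecam1, rose by 0.51. Xist was present in all 6 libraries and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in all 6, under a floor of 3 counts that lies between 0.132 and 0.218 CPM per library.

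In all, 17 of the 28 gene lists tested were called at a preset correlation of 0.01, 10 up and 7 down. With an estimated correlation camera called 0 (lowest adjusted p = 0.0651), with 9 lists under an unadjusted p of 0.05, and fry, which asks whether a list's genes move one way on balance, called 21, among them 15 of the 17 but not NF-kB (adjusted p = 0.494) or type I interferon (adjusted p = 0.205). The loss was not always due to a higher correlation. For p53 targets the estimate was -0.0287, below the preset 0.01, yet camera's unadjusted p went from 7.52e-05 to 0.0123. For myeloid markers it was -0.024, and the unadjusted p went from 4.85e-07 to 0.00597.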

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

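Thinning, removal of GC content and length trends, and leaving out other cells' markers were chosen after the data were seen. The count of called genes kept within 1.5 times of 2712 under every test setting, from 1946 without control replicate 2 to 3492 at an adjusted p under 0.1, and moved only when an absolute log2 fold change of at least 1 was also required (224). Leaving out 1 library gave 1946 to 2902 genes and 15 to 17 lists. DESeq2 called 2181 genes. Rel stayed between -3.65 and -3.43 on the log2 scale. Thinning to the smallest total called 2405 genes and kept 85.1% of the 2672 calls still tested, with 100% in the same direction. Removal of the GC content and length trends kept 96.9% of 2683 calls. Most calls thus held at equal depth and with these trends removed. The excess of higher genes did not hold without the trends, with 1595 higher and 1600 lower.

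The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 2712 genes and the highest other split 0, so 1 split gave as many, and for lists 17 against 14, again 1 split. Other splits called 2 to 14 lists with the preset correlation. Each of them joins 2 libraries of one group with 1 of the other. The group difference then adds to the spread within each side and partly remains between the sides. The values of 0 genes and 2 to 14 lists are therefore not levels to be expected by chance. With an estimated correlation 0 lists were called. A mean of at least 5 CPM left 13 lists, since some lists then hold fewer members.

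Same-numbered libraries had correlations of 0 to 0.08, under 0.1, and not every library correlated best with its own number. With 3 libraries per group this cannot exclude a shared litter or day, so whether the numbers pair the libraries is unknown. The replicate block gave 3178 genes, more than the 2712 without it, and 17 lists.

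Over 141 named genes, 2830 of 2893 alternative values kept direction and side of the threshold, 49 lost the call, 8 gained it and 6 turned. Those were Cd68 (-0.09 without control replicate 1, -0.01 without REL-deleted replicate 3, 0.00 with GC content and length trends removed, leave-one-out range -0.09 to 0.09) and Ppbp (-0.18 with 0.1 added, -0.30 with quantile normalization, -0.94 without REL-deleted replicate 1, leave-one-out range -0.94 to 0.79), 2 genes that did not pass in any of these. Of 528 list values, 488 kept, 26 lost and 11 gained the call and 3 turned without a call, oxidative phosphorylation (adjusted p 0.597 without control replicate 1, 0.305 without REL-deleted replicate 2, leave-one-out range 0.0746 to 0.891) and germinal centre (0.957 without a variance trend). The causes were not tested. A robust variance model was not run for the lists, since camera has none. Depth limits the genes near 1 CPM, which carry most of the largest increases.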

Other observations

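The tests of non-B cell markers for RNA of other cells, of the quiescence gain against T cell markers under 10 CPM, of the remaining Rel reads and of the nearest neighbours of Rel over a range of distances, and the genes in the next paragraph, were chosen after the result was seen. The shared-sequence test was prompted by the low level of Gapdh, before the ribosomal protein levels were compared.

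Among genes with at least 5 CPM in control libraries, the 10 largest increases included genes with varied roles. Serpina3g, a serine protease inhibitor gene, rose from 7.49 ± 0.0750 to 29.0 ± 2.25 CPM, Hspg2, which encodes perlecan, from 22.2 ± 1.35 to 73.3 ± 2.23 CPM, and Abca1, a cholesterol exporter gene, from 36.4 ± 0.912 to 102 ± 2.79 CPM. Cables1, Wnt10b, Asph, B3gnt7, Itgb3 and Fibcd1 rose by 1.85, 1.76, 1.70, 1.52, 1.49 and 1.47 on the log2 scale. Cd19, a member of the B cell identity list and the gene that drives Cre in both groups, fell by 0.47, from 382.2 ± 9.51 to 276.0 ± 14.8 CPM. Its locus carries the Cre insertion, and the number of copies with the insertion was not compared between groups.

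The 4 tested genes nearest to Rel were all about 2-fold higher. Papolg rose from 77.0 to 172 CPM, Pus10 from 65.4 to 132 CPM, Pex13 from 30.9 to 62.7 CPM and 0610010F05Rik from 32.0 to 60.3 CPM, while the next gene, Ahsa2, was at 0.07 on the log2 scale. A local effect of the modified locus, as hypothesised before its neighbours were examined, did not hold for the 20 nearest genes, whose median absolute log2 fold change of 0.16 lay at percentile 90.5 of windows of 20 neighbouring genes, and those of Cd19 at percentile 43.4. A scan over the nearest 2 to 20 genes placed Rel at percentile 99.41 of 11176 genes, so an effect on the closest genes may be present, a hypothesis found and tested on the same data. Pus10 and Pex13 overlap on opposite strands, and neither a loss of c-Rel binding nor donor-strain sequence around the allele was tested.

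Markers of T cells, NK cells and myeloid cells were higher in REL-deleted libraries, and 90.9% of their 33 tested genes (30) lay above control. Some of these genes passed the filter only through the REL-deleted libraries and could only lie above control, so this share is no test of direction. Thinning left the median log2 fold change at 1.89 against 1.96, past the limit set beforehand for arguing against unequal depth. Thinning keeps ratios between scaled libraries on average, whatever their cause, so this outcome does not decide the question. RNA of other cells left after the magnetic purification may contribute, and no test here excludes it. The 22 called quiescence genes gained 489 CPM, 7.98 times the 61.3 CPM of all 14 tested T cell markers, which left the planned test undecided. Lck and Il7r gave 45.8 of the 61.3 CPM. Against the 15.5 CPM (SE 1.24) of the 12 T cell markers under 10 CPM in control libraries, the gain of 489 CPM (SE 40.3) gave a ratio of 31.5. That is past the limit of 10 set for this later test, which argues against T cells as the source of the whole gain. The limit was set without a T cell profile to give the ratio to be expected, and Il7r is in both lists. A T cell share of the gain, also in single genes such as Tcf7, stays open.

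Gapdh stood at 9.07 CPM in control libraries, against 760 CPM for Ldha of the same pathway. The 27 ribosomal protein genes with at least 50% of their 50-base stretches shared with another annotated gene had a median of 101 CPM, which is 22.6% of the 448 CPM of the 10 genes with under 10% shared. Reads shared with near-identical copies may thus have been left out of the counts, although Eef1a1, with 57.9% shared, stood at 6916 CPM and Rps18, with 86.7% shared, at 547 CPM. No biological explanation was tested.

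After Rel, Bcl2l1 fell furthest among genes at 10 CPM or more in control libraries, with a log2 fold change of -3.18, 0.43 from that of Rel, which leaves open whether the remaining Rel reads came from B cells that kept the gene.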
